A study of Mus musculus with 6 samples.

How the data were processed

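RNA was sequenced from cultured 4T1 cells, a mouse mammary carcinoma line of BALB/c origin, in 2 groups of 3 libraries: cells with a vector control and cells in which Atm, the gene of the kinase that signals DNA double-strand breaks, was knocked out (ATM KO). Per the labels' protocols, total RNA was extracted with RNeasy Plus kits and libraries were made by standard Illumina protocols. The labels do not say whether the 3 libraries of a group came from separate cultures, clones or days, so p-values measure the spread between these libraries, which may be technical. Each sample was placed in its group by its title.

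The submitters' processing notes name Trim Galore, cutadapt, STAR, SAMtools, HTSeq and DESeq2 and the genome builds GRCm38 and mm9, without versions, order or roles. The deposited values are a signal per gene: gene read counts that the authors divided by 1 factor per library. This was read from the values, which are whole multiples of a fixed step in each library, and the step gives back the whole reads. All values (100%) came out whole within 0.01 reads. Each file lists 13405 genes with an Ensembl gene ID, a symbol and a coding flag, and the rule by which those genes were kept is not given in the sources used here. Of these IDs, 13249 (98.8%) are in GENCODE M21 on GRCm38, which gave the coordinates printed here; the files themselves hold none. Whether counting used strand is not stated, so overlapping and antisense genes cannot be told apart. Genes with close copies (Apol9a and Apol9b, Gbp2 and its neighbours, the Oas1 and H2-Q families, replication-dependent histones) have uncertain counts because reads can be lost or shared between copies. Gapdh, which has many processed pseudogenes, stood at only 343 ± 42.6 normalized counts in the controls beside 88639 ± 18436 for Actb.

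The reads recovered per library were 29500267, 30042957 and 27264975 in vector controls 1 to 3 and 32341508, 26223323 and 22494919 in ATM KO 1 to 3. The values were compared on the log2(value + 1) scale, which understates changes of genes with low values. Of the genes listed, 12149 had a mean value of at least 10 over the 6 libraries and were tested (11326 of them coding), and 15 were at 0 in every library.

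The tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined, except where the text says otherwise. The main test was limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean-variance trend, 2-sided), ATM KO minus vector control, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. On the recovered reads, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run as alternatives. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 24 lists with at least 5 tested members, with camera at a correlation estimated per list and fry, a self-contained test, beside it. The 26 lists cover interferon-stimulated genes, interferon-gamma type GTPases and targets, nucleic acid sensing, cytokines, class I antigen presentation, mitochondrially encoded mRNAs, mitochondrial DNA maintenance, oxidative phosphorylation, p53 targets, DNA damage response, S phase, G2/M, NF-kappa-B targets, oxidative stress, integrated stress, cholesterol biosynthesis, glycolysis and hypoxia, epithelial and mesenchymal markers, YAP and TGF-beta targets, immune, fibroblast and endothelial markers, ribosomal proteins, immediate early genes, heat shock chaperones and histones. Some genes stand in more than 1 list, such as Ifih1, Tap1, Psmb8 and Mmp9.

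The genes named are Atm; a fixed panel of the sensing and interferon pathway (Tfam, Cgas, Sting1, Tbk1, Irf3, Ifnb1, Cxcl10, Ccl5, Isg15, Ifit1, Ifit3, Irf7, Cd274); the 8 largest rises and 8 largest falls past the threshold with a mean of at least 50 in the higher group and no overlap between the groups, leaving out predicted, clone-named and pseudogene symbols; and from each list up to 4 members past the threshold or, where none passes, up to 3 with the highest mean. Because limma called no gene, the parts that need a call were also applied to the DESeq2 calls, a step added after the results were seen.

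The scripts were tested on simulated counts for the 12149 genes, with 100 genes changed 2-fold and 100 changed 4-fold. With the spread found between libraries of a group, limma recovered 3% of the 2-fold and 52% of the 4-fold changes and called 5 of 11949 unchanged genes. DESeq2 recovered 29% and 85% and called 44 unchanged genes. With that dispersion cut to 10%, limma recovered 81% of the 2-fold changes and 98% of the 4-fold changes. In a test of camera, a list of 40 genes raised by 0.5 on the log2 scale had an adjusted p of 1.57e-07 and none of 20 unchanged lists (0) was called. The simulated genes were drawn independently, so this test could not show false list calls that come from correlation between genes. In the real lists that correlation was estimated at up to 0.79.

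The alternatives were a replicate block, pseudocounts of 0.5 and 10, no filter and a filter at a mean of 50, rescaling by median ratios, quantile normalization, equal totals, limma without the trend, each library left out in turn, edgeR and DESeq2. Added after the data were seen were 1 surrogate variable (sva 3.50.0), the mean of the hypoxia list as a covariate, and a fit without vector control 1 and ATM KO 2. Groups of 3 are too small for an outlier test, and the series holds 1 contrast, so no difference between contrasts was tested.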

Results

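The series holds 6 RNA-seq libraries of 4T1 mouse mammary carcinoma cells grown in vitro, 3 from vector control cells and 3 from ATM KO cells. Its title links loss of ATM to mitochondrial DNA leakage and activation of cGAS-STING, the cytosolic DNA sensing pathway that induces type I interferon. The comparison of ATM KO with vector control cells therefore addresses interferon, nucleic acid sensing, cytokine, antigen presentation and mitochondrial genes. Between 22494919 and 32341508 reads per library were assigned to the listed genes. Group values below are mean normalized read counts ± SD over the 3 libraries of a group, and fold changes are ATM KO minus vector control on the log2(value + 1) scale with their SE.

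Atm mRNA was not lower in the knockout cells. Atm (ENSMUSG00000034218, chromosome 9, 53439149 to 53536740, minus strand, GRCm38) stood at 1703 ± 243 in vector control and 1923 ± 316 in ATM KO cells, a log2 difference of 0.17 (SE 0.19). Its values were 1978, 1613 and 1519 in vector controls 1 to 3 and 1959, 2220 and 1591 in ATM KO 1 to 3. The difference was smaller than the spread between libraries (adjusted p = 0.999, limma), and the groups overlapped. A knockout by frameshift need not lower the mRNA, and gene-level values do not show a small deletion, so Atm does not check the labels here.

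Vector control 1 differed from the other controls more than any knockout library differed from them. The first principal component carried 59.4% of the variance and placed vector control 1 at -86.2 and ATM KO 2 at -41.5, against 36.9 and 37.0 for vector controls 2 and 3, 3.19 for ATM KO 1 and 50.7 for ATM KO 3. The second component, with 18.9% of the variance, parted the groups: the controls lay at -8.36, -32.9 and -32.8 and ATM KO 1 to 3 at 16.5, 13.7 and 43.8. Across genes, the correlation of log2 values was 0.997 between vector controls 2 and 3 and 0.914 between vector controls 1 and 2. Vector controls 2 and 3 still differed beyond counting noise, with a chi-square per gene of 16.4 (the other pairs lay between 77.0 and 368), and were kept as separate samples. That argues against 1 library sequenced again, but not against 2 preparations from 1 culture. In that case the controls would hold fewer than 3 independent samples, and their SDs and the p-values could mislead. Along the same axis, hypoxia targets were low in vector control 1, with a median deviation of -1.20 on the log2 scale, and in ATM KO 2 (-0.71), but high in vector controls 2 and 3 (0.74 and 0.72) and ATM KO 3 (0.50).

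**Figure D1:**
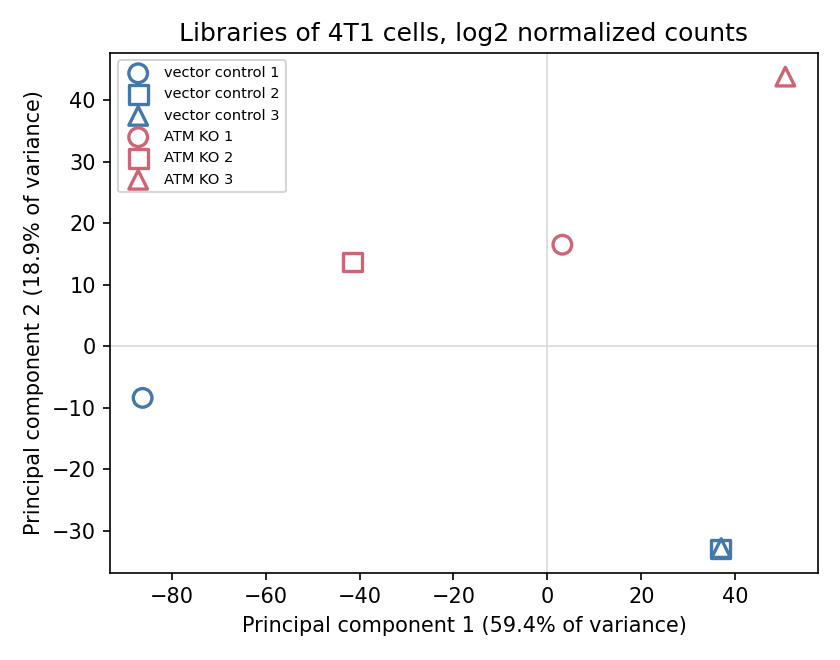
First against second principal component of the log2 normalized counts of the tested genes, 1 point per library, colour for the group and shape for the replicate number. The symbols of vector controls 2 and 3 overlie at 36.9 and 37.0 on the first component, vector control 1 lies at -86.2, and all ATM KO libraries lie above all controls on the second.

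Nt5e, Sept6, Errfi1 and Pmepa1 were higher in every ATM KO library than in every control. Nt5e, which encodes the ecto-5'-nucleotidase CD73 that makes extracellular adenosine, stood at 1651 ± 219.5 in control and 3685 ± 135 in ATM KO cells (log2 1.17, SE 0.16). Sept6, a septin of the cytoskeleton, stood at 234 ± 19.2 and 1212 ± 458 (log2 2.30, SE 0.31). Errfi1, a feedback inhibitor of the EGF receptor, had values of 4383 ± 315 and 7845 ± 494 (log2 0.84, SE 0.13), and Pmepa1, a TGF-beta target, 4093 ± 83.0 and 6600 ± 262 (log2 0.69, SE 0.12). All 4 were singled out after their values were seen, Pmepa1 also through the DESeq2 calls of its list. The calls that follow use the same libraries and are not separate support. DESeq2 on the recovered reads called all 4, with adjusted p of 1.24e-07 for Nt5e, 2.34e-08 for Sept6, 1.68e-05 for Errfi1 and 3.31e-06 for Pmepa1. Limma called the same 4 when 1 surrogate variable, added after the data were seen, entered the model (adjusted p between 0.0263 for Nt5e and 0.0452 for Pmepa1).

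No gene passed limma's threshold. The smallest adjusted p was 0.799, and 505 genes had an unadjusted p under 0.05 (336 higher, 169 lower) where 607 would be met by chance. By edgeR 0 genes passed and 522 had an unadjusted p under 0.05. DESeq2 called 84 genes, 68 higher and 16 lower in ATM KO cells, 55 of them by at least 2-fold, and 717 genes had an unadjusted p under 0.05. In 81 of the 84 the groups did not overlap. Over all tested genes, 1358 (11.2%) had groups that did not overlap, where chance gives 10%. In simulated data with this spread, DESeq2 also called 44 unchanged genes, so single calls are provisional, and limma found 3% of 2-fold changes, so changes of that size are mostly out of its reach.

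The largest rises among the DESeq2 calls came from genes with low values in control cells. Gpr123 stood at 1.67 ± 1.499 in control and 153 ± 149 in ATM KO cells, and Inhbb, the beta-B subunit of inhibin and activin, at 2.31 ± 1.46 and 138 ± 170. Both knockout means rest largely on ATM KO 3 (312 and 334), without which the log2 fold changes were 4.402 instead of 5.30 for Gpr123 and 3.69 instead of 4.71 for Inhbb. Sulf2, an extracellular heparan sulfate sulfatase, stood at 23.3 ± 3.45 and 557 ± 752, with 1424 in ATM KO 3 against 152 and 93.4 in ATM KO 1 and 2. Syt2 was even across the knockout libraries, at 5.26 ± 2.34 against 53.4 ± 6.94 (log2 3.18, SE 0.44). Wisp2, Akna, Apol9a and Myo7a made up the rest of the 8, Myo7a with 39.3 ± 19.1 in control cells and 552, 58.4 and 573 in ATM KO 1 to 3. The log2 fold change of Sulf2 was 2.31 without ATM KO 3 and 3.50 with it. Among the falls, Bmp7, a secreted TGF-beta family ligand, stood at 544 ± 422 and 30.3 ± 24.8, with 57.4 in vector control 1 near the 40.2 and 48.6 of ATM KO 1 and 3, and the membrane carbonic anhydrase Car12 at 1109 ± 548 and 250 ± 78.0. Magea8, at 72.6 and 76.7 in vector controls 2 and 3 but 0.973 in vector control 1, was at 0 in every ATM KO library. Rassf4 and Tubg2 stood at 79.0 ± 64.6 and 89.0 ± 36.8 in control cells and at 0.993 ± 1.07 and 4.13 ± 6.09 in ATM KO cells, and Rassf4 was at 4.87 in vector control 1. The falls of Magea8, Rassf4 and Bmp7 thus rest on vector controls 2 and 3, and when 1 library was left out their log2 fold changes ranged from -6.24 to -3.59, -6.02 to -3.82 and -5.41 to -2.87. Smaller falls were those of Arhgef1 (log2 -0.62, SE 0.14), the mitotic entry gene Cdca3 (log2 -0.61, SE 0.14) and Snrpn (log2 -0.59, SE 0.14). All of these genes passed DESeq2 and failed limma.

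Interferon-stimulated genes rose as a group in ATM KO cells. Of 66 tested members, 56 had positive and 10 negative log2 fold changes, with a median of 0.48, and in 21 every ATM KO library lay above every control while in 0 every one lay below. Isg15, a ubiquitin-like interferon effector (chromosome 4, 156199424 to 156200818), went from 74.3 ± 11.2 to 274 ± 113 (log2 1.78, SE 0.40), Oasl2 from 55.3 ± 36.1 to 319 ± 64.0 and Slfn2 from 65.6 ± 41.6 to 353 ± 173. Ifih1, the cytosolic double-stranded RNA sensor MDA5, went from 338 ± 45.2 to 616 ± 74.4. Apol9a and Apol9b, near-identical copies whose reads may be shared, had log2 fold changes of 2.64 (SE 0.43) and 2.40 (SE 0.44). These 6 members passed DESeq2 (Isg15 at an adjusted p of 0.00481), 0 passed limma over all genes, and 2, Apol9a and Apol9b, passed limma when adjusted over the list alone. The most abundant members differed by less than their spread, with Rnf213 at 6034 ± 480 and 6535 ± 1730 and Trim25 at 4708 ± 650 and 4896 ± 213. The list passed camera at an adjusted p of 1.71e-11, with an adjusted p of 0.304 when the correlation was estimated. Vector control 1 carried the lowest values, with a median deviation of -1.05 against 0.09 and 0.11 in the other controls and 0.48, 0.31 and 0.27 in ATM KO cells, and without it the median fell to 0.14 (camera adjusted p = 0.0179) and the log2 fold changes of Oasl2 and Slfn2 to 2.04 from 2.84 and 1.84 from 2.61.

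Of the fixed interferon panel, Ifit1 stood at 35.4 ± 25.8 and 103 ± 16.5 (log2 1.98, SE 0.82), with 5.84 in vector control 1, without which the log2 fold change was 1.02, and every ATM KO library above every control. Ifit3 stood at 8.52 ± 3.87 and 16.3 ± 5.37, and Irf7, the transcription factor that amplifies interferon induction, at 50.6 ± 37.1 and 73.3 ± 23.97. Irf7 was at 7.78 in vector control 1, and without that library its log2 fold change was -0.04 instead of 0.98. Cd274, which encodes PD-L1, stood at 37.8 ± 2.48 and 49.4 ± 11.9. None of these 4 passed limma, edgeR or DESeq2. Ifnb1 was not among the listed genes and was not analysed here.

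The interferon-gamma type GTPases and targets rose with a median of 0.98 over 25 tested members, 23 of them positive. Gbp9, an interferon-inducible guanylate-binding protein, went from 138 ± 28.1 to 463 ± 183 and passed DESeq2 (adjusted p = 0.00747). Gbp2, named after its values were seen, stood at 74.1 ± 45.4 and 275 ± 44.2, and the transcription factor Irf1 at 1280 ± 663 and 2259 ± 535, and neither passed. Both were lowest in vector control 1 (25.3 and 517), and without it the log2 fold change of Gbp2 was 1.48 instead of 2.11. The list passed camera at an adjusted p of 4.91e-08, with an adjusted p of 0.304 at an estimated correlation. Its median was lowest in vector control 1 (-1.61), and without that library the median was 0.19 and the adjusted p reached 0.0661.

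The nucleic acid sensing genes themselves did not pass as a group, with 19 positive and 21 negative of 40 tested members, a median of -0.02 beside a mean of 0.15, and a camera adjusted p of 0.272. Sting1 (listed as Tmem173, chromosome 18, 35733679 to 35740554), the adaptor that relays the cGAS signal, had the largest difference among the panel genes of this list. Tmem173 stood at 246, 250 and 267 in the controls and 356, 568 and 520 in ATM KO cells, a log2 fold change of 0.89 (SE 0.24), which missed the threshold by DESeq2 (adjusted p = 0.0744). Cgas (listed as Mb21d1, chromosome 9, 78430526 to 78443237) stood at 668 ± 423 and 719 ± 301, and its direction turned when vector control 2, vector control 3 or ATM KO 2 was left out. Tbk1, the kinase downstream of STING, stood at 1828 ± 203 and 2084 ± 167. Its substrate Irf3 stood at 682 ± 71.6 and 840 ± 43.7, with every ATM KO library above every control (log2 0.31, SE 0.17). The abundant members Dhx9, G3bp1 and Samhd1 had log2 fold changes of 0.15, -0.07 and -0.03. Ifih1, which stands in this list too, was its only DESeq2 call.

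Cytokine and chemokine genes rose as a group, with 19 positive of 22 tested members and a median of 0.66. The macrophage growth factor Csf1 stood at 5822 ± 1163 and 9693 ± 2711 (log2 0.72, SE 0.26), with every ATM KO library above every control, and Cxcl16 at 4660 ± 870 and 6977 ± 2322. Cxcl5, the member with the highest values, overlapped, at 24048 ± 24660 and 26575 ± 6069 with 52523 in vector control 1. Ccl5, a T cell chemokine, stood at 23.1 ± 3.08 and 71.4 ± 27.9 (log2 1.503, SE 0.43), again with no overlap. Cxcl10 stood at 22.2 ± 3.55 and 74.3 ± 64.6 and overlapped the controls through ATM KO 3. Its knockout mean rests on ATM KO 2 (146, against 54.8 and 21.8 in ATM KO 1 and 3), without which the log2 fold change was 0.63 instead of 1.31, and it was 1.98 without ATM KO 3. Csf2, which encodes GM-CSF and was singled out after its values were seen, stood at 6.86 ± 7.55 and 50.1 ± 18.6, with 15.6 in vector control 1, without which the log2 fold change was 3.80 instead of 3.05. None of the members passed limma or DESeq2 adjusted over all genes (0 of 22). Adjusted over the list alone, 0 passed limma and 3 passed DESeq2. The list passed camera at an adjusted p of 2.61e-05, with an unadjusted p of 0.00777 and an adjusted p of 0.187 at an estimated correlation. Unlike the interferon lists, its median was larger without vector control 1, at 0.73.

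Class I antigen presentation genes were higher by a median of 0.33, with 28 positive of 32 tested members. Tapbp, which encodes tapasin, the bridge between the peptide transporter and class I molecules, went from 3593 ± 209 to 5264 ± 324 (log2 0.55, SE 0.13), and the related editor Tapbpl from 194 ± 3.20 to 324 ± 28.2 (log2 0.73, SE 0.20). Both passed DESeq2 (adjusted p of 0.00929 and 0.0239). The chaperones of the list went both ways, with Pdia3 at 18502 ± 248 and 22099 ± 806 and Canx at 27298 ± 1408 and 22885 ± 3431, and neither passed. The list passed camera at an adjusted p of 2.61e-05, with an adjusted p of 0.304 at an estimated correlation. Without vector control 1 the median was 0.14 and the adjusted p 0.300.

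**Figure D2:**
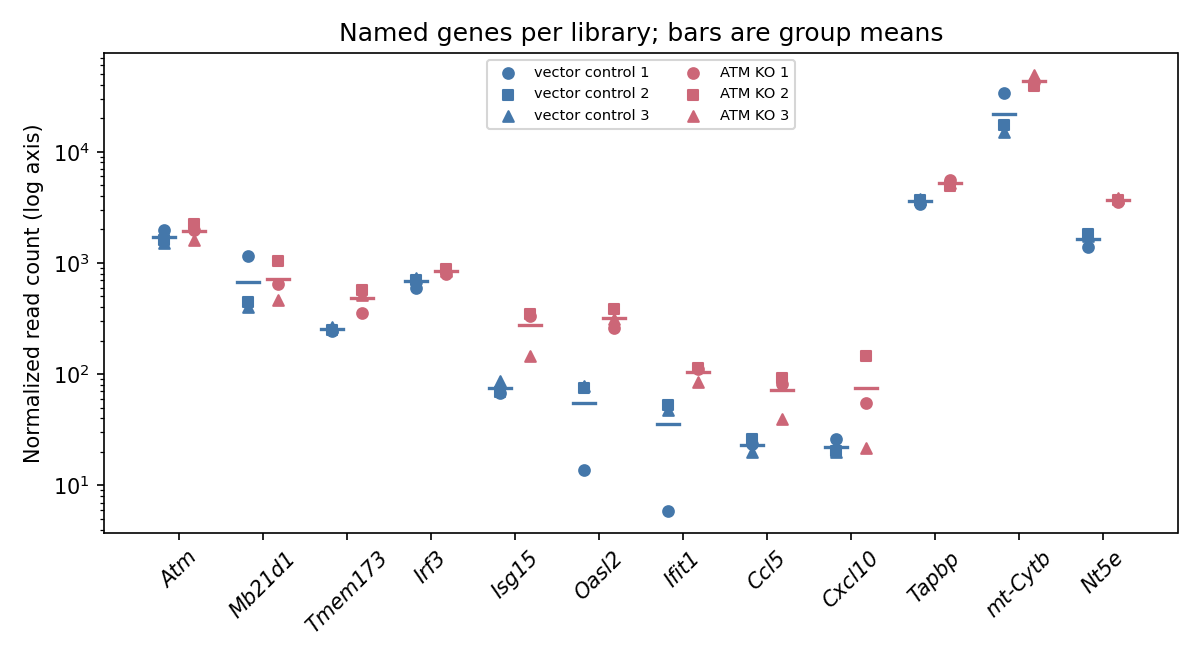
Normalized read counts on a log axis for 12 named genes in each library, with a bar at the mean of each group of 3. Isg15, Oasl2, Ifit1, Ccl5, Tmem173, Irf3, Tapbp, mt-Cytb and Nt5e show no overlap between the groups, while Atm, Mb21d1 and Cxcl10 overlap.

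Mitochondrially encoded mRNAs rose in ATM KO cells, with all 7 tested members positive and a median of 0.96. The list names 13 mRNAs, of which only these 7 were among the genes given. In 4 of the 7 every ATM KO library lay above every control. The most abundant, mt-Nd1, overlapped, at 77411.5 in vector control 1 against 69029, 62708 and 73110 in ATM KO 1 to 3. So did mt-Co1, at 43898.5 in vector control 1 and 33161 in ATM KO 2. The cytochrome b mRNA mt-Cytb (mitochondrial genome, 14145 to 15288) stood at 21996 ± 10226 and 43643 ± 5084 (log2 1.08, SE 0.31), and mt-Nd6, the member on the other strand, at 5546 ± 242 and 8042 ± 689 (log2 0.53, SE 0.13). When limma was adjusted over the list alone, 4 members passed, mt-Nd2, mt-Nd4, mt-Nd6 and mt-Cytb, all at an adjusted p of 0.0231, and 0 passed over all genes. By DESeq2 mt-Nd6 passed (adjusted p = 0.0426). The large ribosomal RNA mt-Rnr2, outside the list and named after its values were seen, stood at 15475 ± 6260 and 31542 ± 4117. The list passed camera at an adjusted p of 8.50e-09, with an unadjusted p of 0.0409 and an adjusted p of 0.304 at an estimated correlation. Vector controls 2 and 3 had the lowest medians (-0.73 and -0.999), vector control 1 stood at 0.14 and ATM KO cells at 0.46, 0.39 and 0.71. The median log2 fold change was 0.60 without vector control 3 and 1.38 without vector control 1.

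Nuclear genes of the mitochondrion showed no such rise. Tfam (chromosome 10, 71225464 to 71238280), which packages mitochondrial DNA, stood at 1750 ± 163 and 1698 ± 225. Its list of mitochondrial DNA maintenance and transcription genes had 15 positive and 27 negative of 42 members, a median of -0.05 and a camera adjusted p of 0.102, with Vdac1 at a log2 fold change of -0.35 (SE 0.18) and Lonp1 at -0.46 (SE 0.23). Nuclear-encoded oxidative phosphorylation subunits fell slightly, with 59 negative of 75, a median of -0.12 and a camera adjusted p of 3.23e-04, and 0.550 as the adjusted p at an estimated correlation. The call was lost without ATM KO 3 (adjusted p = 0.556) or vector control 1 (0.0661). Atp5b and Atp5a1 had log2 fold changes of -0.34 and -0.28. The maintenance list passed as lower without vector control 2 (0.0158), vector control 3 (0.00951) or ATM KO 2 (0.00507), and turned direction without vector control 1 (0.686) or ATM KO 3 (0.815).

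Mitotic genes were lower as a group, with 0 positive and 44 negative members and a median of -0.27. Here too vector control 1 stood apart from the other controls, with a median deviation of -0.13 against 0.30 in both, beside -0.05, -0.12 and -0.25 in ATM KO cells, and without it the median was -0.43. Anln stood at 31712 ± 5031 and 23828 ± 4203, Mki67 at 29803 ± 8634 and 23653 ± 1430 and Top2a at 50443 ± 13716 and 42333 ± 7821, none past the threshold. The list passed camera at an adjusted p of 2.72e-11, with an adjusted p of 0.304 at an estimated correlation. S phase genes (33 negative of 48, median -0.13) and DNA damage response genes (36 negative of 55, median -0.11) passed camera at adjusted p of 0.0190 and 0.0188, but had adjusted p of 0.671 and 0.550 at an estimated correlation. Both turned in camera's direction without ATM KO 3 (adjusted p = 0.140 and 0.991), the library with the lowest S phase median (-0.50). The median of the DNA damage list itself stayed negative there (-0.03). Without vector control 1 the S phase list turned too (0.868) and the DNA damage list missed the threshold (0.419). The p53 targets did not pass as a list (15 positive of 27, camera adjusted p = 0.621). DESeq2 called 2 of its members, Sulf2 and Phlda3, a p53-induced inhibitor of AKT, at 231 ± 31.4 and 412 ± 22.1.

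Cholesterol biosynthesis genes were lower, with 20 negative of 23 and a median of -0.34 (camera adjusted p = 1.47e-06, and 0.304 as the adjusted p at an estimated correlation). Srebf2, their master regulator, stood at 12261 ± 2416 and 9749 ± 2416, Hmgcs1 at 10783 ± 144 and 9450 ± 3269. The list was low in ATM KO 1 and 2 (medians -0.29 and -0.33) but not in ATM KO 3 (0.13). Integrated stress and unfolded protein response genes were also lower (27 negative of 39, median -0.15, camera adjusted p = 0.00639, and 0.304 with an estimated correlation), with Hspa5 at a log2 fold change of -0.15 and Hsp90b1 at -0.21. That call was lost without vector control 1 (0.331) or ATM KO 3 (0.171). Hypoxia and glycolysis genes had 24 negative of 36 and a median of -0.16 (adjusted p = 0.0301, and 0.671 with an estimated correlation). That list varied more between the controls than between the groups, its median was -0.79 without vector control 1 (5.09e-10), and its direction turned without vector control 2 (0.940), vector control 3 (0.924) or ATM KO 2 (0.990). Oxidative stress genes did not pass (adjusted p = 0.831), although Mgst1, a microsomal glutathione transferase, went from 158 ± 67.0 to 535 ± 151 and passed DESeq2 (adjusted p = 0.0151).

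NF-kappa-B targets rose, with 25 positive of 34 and a median of 0.32 (camera adjusted p = 9.44e-05, and 0.299 as the adjusted p with an estimated correlation). The inhibitor gene Nfkbie went from 712 ± 168 to 1399 ± 93.3 and passed DESeq2 (adjusted p = 0.0220). Mmp9, a matrix metalloproteinase, stood at 7411 ± 5516 and 21314 ± 5697, with no overlap and no call. Mmp9 was at 1042 in vector control 1, without which its log2 fold change was 0.98 instead of 2.09 and the list had a median of 0.19 (adjusted p = 0.0353). YAP and TGF-beta targets had 24 positive of 30 and a median of 0.26 (adjusted p = 1.03e-04, and 0.304 with an estimated correlation), with Pmepa1 the 1 member that passed limma adjusted over the list alone. Mesenchymal and matrix genes had 19 positive of 26 and a median of 0.39 (adjusted p = 0.00279, and 0.404 with an estimated correlation), and epithelial markers 27 positive of 42 and a median of 0.09 (adjusted p = 0.0340, and 0.666 with an estimated correlation). Without vector control 1 the adjusted p was 0.102 for YAP and TGF-beta targets, 0.475 for mesenchymal genes and 0.944, with the direction turned, for epithelial markers. The epithelial call was also lost without ATM KO 1 (0.102) or ATM KO 3 (0.815). Fn1 stood at 67307 ± 35491 and 76788 ± 34209, and Krt18 at 31136 ± 7792 and 37491 ± 8248.

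**Figure D3:**
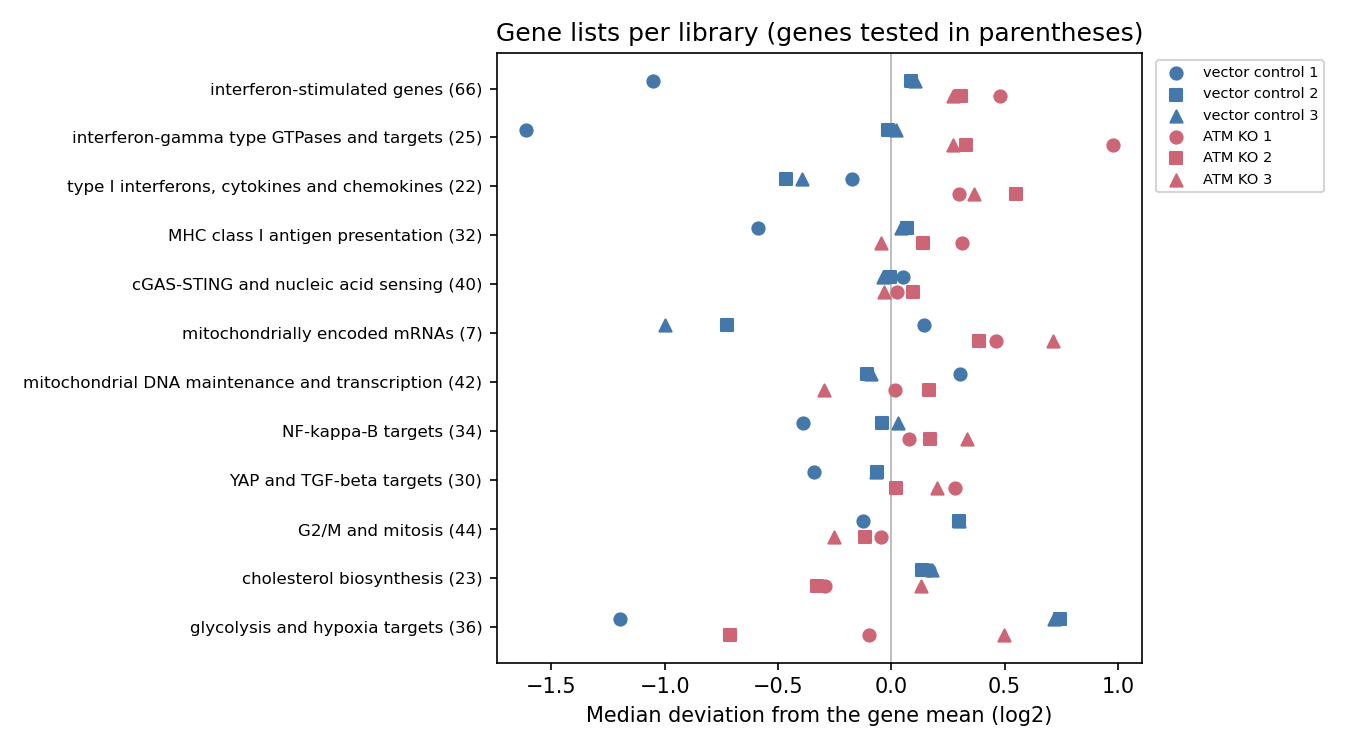
Median over the tested genes of each list of the deviation of log2(value + 1) from the gene's mean over the 6 libraries, 1 point per library, with the number of tested genes in parentheses. Vector control 1 stands at -1.05 for interferon-stimulated genes and -1.61 for the interferon-gamma type list, and the ATM KO libraries lie above all controls for mitochondrially encoded mRNAs.

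Markers of other cell types gave no common direction. Of 30 immune markers 8 were listed and 4 tested, and these moved apart: Csf1r stood at 331 ± 88.9 and 841 ± 357, Cd14 had a log2 fold change of 0.39, and Cd68 and Lcp1 stood at 794 ± 429 and 1441 ± 116 in control and 432 ± 324 and 747 ± 612 in ATM KO cells. Coro1a, a leukocyte actin regulator, lay between 5.12 and 12.7 in all libraries. Of 22 fibroblast and endothelial markers 4 were tested, with a median of 0.43 and no call, and Flt1 and Pdgfra among them; without vector control 1 the median was -0.23. Of the lists that track handling, cytosolic ribosomal protein genes were lower (50 negative of 73, median -0.16, adjusted p = 2.25e-04, and 0.304 with an estimated correlation), immediate early genes higher (20 positive of 26, adjusted p = 0.00616, and 0.304 with an estimated correlation) and histone genes lower (12 negative of 15, adjusted p = 0.0343, and 0.447 with an estimated correlation). Heat shock chaperones did not pass (adjusted p = 0.380). Immediate early genes were lowest in vector control 1, with a median of -0.72, and their call was lost without it (0.312) or without ATM KO 3 (0.189). The histone call was lost without vector control 1 (0.331), vector control 2 (0.340), ATM KO 1 (0.0721) or ATM KO 2 (0.244).

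In all, 19 of 24 lists passed camera at the preset correlation, 10 higher and 9 lower. With an estimated correlation 0 passed after adjustment, and 3 had an unadjusted p under 0.05, the cytokine, mitochondrially encoded and NF-kappa-B lists. By fry 0 lists passed after adjustment and the same number, 3, had an unadjusted p under 0.05. Without vector control 1, 8 lists passed camera.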

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

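The fits with a surrogate variable, with the hypoxia list as a covariate and without vector control 1 and ATM KO 2 were chosen after the data were seen. No gene passed limma under the replicate block, pseudocount, filter, rescaling, trend or leave-one-out alternatives, and edgeR called 0, where DESeq2 called 84 genes (68 higher, 16 lower, 55 by at least 2-fold). With 1 surrogate variable limma called 18 (15 higher, 3 lower, 12 by at least 2-fold), 9 of them shared with DESeq2, and with the hypoxia covariate 221 (193 higher, 28 lower, 123 by at least 2-fold), 45 of them shared with DESeq2. The cause of these differences was not tested. Rescaling moved the median gene by at most 0.02 on the log2 scale and equal totals moved libraries by at most 0.04.

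With a replicate block limma called 0 genes and 19 lists passed, as without it. After the mean of its group was subtracted from each gene, samples with the same number correlated at -0.02, -0.58 and 0.53. These values show no pairing by number, but they cannot exclude one. Vector controls 2 and 3 can hardly be told apart on this measure, at -0.58 and -0.59 with ATM KO 2 and 0.53 each with ATM KO 3. On that measure vector control 1 correlated best with ATM KO 2 (0.61).

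With an estimated correlation the adjusted p was 0.304 for the interferon-stimulated, class I and mitochondrially encoded lists and 0.187 for cytokines, and by fry it was 0.379 for interferon-stimulated genes, 0.281 for mitochondrially encoded mRNAs and 0.0759 for cytokines. With camera at the preset correlation these 3 lists passed under the replicate block, the pseudocount of 10, the filter at 50, quantile normalization, no trend, each library left out and the 3 added fits; the interferon-stimulated list had 5.32e-18 to 0.0179 when 1 library was left out, the latter without vector control 1. Lists were not run under the other alternatives. When 1 library was left out the medians of the class I, interferon-gamma type and cholesterol lists were lowest in size without vector control 1 (0.14 and 0.19) and ATM KO 2 (-0.18). The class I list missed without vector control 1 (0.300; leave-one-out range 4.45e-07 to 0.300) and without vector control 1 and ATM KO 2 (0.239). The mitochondrial DNA maintenance list, not past the threshold in the main test, ranged from 0.00507 (lower, without ATM KO 2) to 0.815 (higher, without ATM KO 3), was lower at 0.0158 without vector control 2 and 0.00951 without vector control 3, and was lower at 0.0111 with the hypoxia covariate.

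Directions turned when 1 library was left out for Tfam (log2 -0.15 to 0.040), Irf7 (-0.035 to 1.497) and Cgas (Mb21d1; -0.12 to 0.68, and -0.029 with the hypoxia covariate). So did the camera directions of the S phase (adjusted p 1.41e-05 to 0.868), epithelial (1.85e-04 to 0.944), oxidative stress (0.420 to 0.940), hypoxia (5.09e-10 to 0.990, and 0.123 with its own mean as covariate), heat shock (0.0661 to 0.940) and DNA damage lists (0.00102 to 0.991). The median of the DNA damage list stayed negative whichever library was left out. Lists past the threshold numbered 16 with the filter at 50, where the hypoxia (0.142), epithelial (0.251) and histone (0.310) lists were lost, 17 with quantile normalization, where the S phase (0.128) and hypoxia (0.0578) lists were lost, 8 without vector control 1, 13 without ATM KO 3 and 17 to 19 without any other library, 15 with the surrogate variable, 18 with the hypoxia covariate and 14 without vector control 1 and ATM KO 2. The cause of these changes was not tested.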

Other observations

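The fit with the hypoxia covariate, the genes named from it and the tests on growth state, on an exchange of vector control 1 with ATM KO 3, on interferon-stimulated genes and on library depth were chosen after the results were seen. With the mean of the hypoxia list as a covariate, limma called 221 genes, 193 higher and 28 lower in ATM KO cells, and in 97 of them the groups did not overlap without it. Of the interferon-stimulated genes, 10 of 66 tested members were called, all higher (Fisher's exact test, adjusted p = 7.29e-06 over the 26 lists, which treats members as independent although their estimated correlation was 0.40). Of the 6 members that passed DESeq2, Apol9a, Apol9b and Oasl2 were among them, and Ifih1, Slfn2 and Isg15 missed the threshold. In 3 of the 10, Trim21, Dtx3l and Ifi203, the groups overlapped. The others included Samd9l (log2 1.39, SE 0.11), Parp14 (1.39, SE 0.21), the ISG15-activating enzyme Uba7 (2.13, SE 0.25) and Zbp1 (3.09, SE 0.40), a sensor of Z-form nucleic acid with low counts (6.70 ± 5.83 and 32.3 ± 15.3), which by DESeq2 without the covariate had adjusted p of 0.344, 0.711, 0.657 and 0.816. Of the interferon-gamma type list 4 of 25 were called (Fisher's exact test, adjusted p = 0.0130). Here too members were treated as independent, although their estimated correlation was 0.48. The 4 were Gbp9 and Gbp2 with no overlap, and Ifngr1 and Jak2 with overlap, Jak2 at 5478 ± 3358 and 5452 ± 2266 before the covariate. Of YAP and TGF-beta targets 4 of 30 were called (adjusted p = 0.0175): Pmepa1 and Tgfb2 with no overlap, and Ltbp2 and Tgfb3 with overlap and log2 fold changes of 0.42 (SE 0.66) and 0.32 (SE 0.70) without the covariate.

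Other genes called in that fit stand outside the interferon lists. Tgm2, a transglutaminase, had the smallest adjusted p (0.00469; log2 2.17, SE 0.09, against 1.76, SE 0.84 without the covariate), and its groups overlapped. The basal keratin gene Krt14 (log2 2.52, SE 0.15; 496 ± 300 and 1968 ± 520), Col7a1 (1.44, SE 0.08), the secreted Chi3l1 (2.60, SE 0.32; 52.9 ± 8.59 and 333 ± 108) and Nt5e (1.21, SE 0.08) were higher. Among the genes called lower were Srebf1 (-0.63, SE 0.08), the lipogenic transcription factor, Got1 (-0.82, SE 0.09), Mitf (-0.87, SE 0.13), and Atf4, Slc7a5 and Slc3a2 of the integrated stress list (-0.72, -0.68 and -0.47), with overlap for Atf4 and Slc7a5. The fibroblast marker Pdgfra was called higher too (0.91, SE 0.12; 1 of the 4 fibroblast and endothelial markers tested), with overlap. By DESeq2 without the covariate, Chi3l1 and Nt5e passed (adjusted p of 2.34e-08 and 1.24e-07), but Tgm2 (0.818), Krt14 (0.0641) and Col7a1 (0.411) did not. Nor did Srebf1 (0.0870), Got1 (0.326) and Mitf (0.151), or Atf4, Slc7a5, Slc3a2 and Pdgfra (0.9999 for each). The covariate rests on the hypoxia list, so the fits of its own members Car9 and Bnip3 cannot be read.

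Other splits of the 6 libraries number 10 with the real one, too few for a share under 0.05. For limma, 3 splits gave at least the real 505 genes at an unadjusted p under 0.05, and the highest other gave 4372. For DESeq2, 2 splits gave at least 84 genes, and the highest other gave 3208: vector control 1, ATM KO 1 and ATM KO 2 against the rest, which by limma gave 1097 genes and is the grouping with the labels of vector control 1 and ATM KO 3 exchanged. With the hypoxia covariate, 1 split, the real one, gave 221 genes and the highest other gave 0. These counts do not decide, because the same covariate entered every split and itself parts the libraries like the split with 3208 calls. It was -1.30, -0.08 and -0.84 in vector control 1, ATM KO 1 and ATM KO 2, against 0.88, 0.90 and 0.44 in vector controls 2 and 3 and ATM KO 3. Little difference was thus left for that split to show. For the camera p of the interferon-stimulated list, 3 splits gave at least the real -log10 p of 12.1, and the highest other gave 20.1. For lists past the threshold, 1 split, the real one, gave 19 and the highest other gave 15.

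Vector control 1 stood apart from the other controls on the axis that carried 59.4% of the variance. Removing trends with GC content and transcript length kept 96.0% of that component, which argues against such a bias. Exchanging vector control 1 with ATM KO 2 left 10 DESeq2 calls where the labelled groups gave 84, the outcome set beforehand as arguing against that exchange. Both libraries lie on the same side of that axis, so few calls could follow whichever labels are right, and the count does not decide. Exchanging vector control 1 with ATM KO 3 gave 3208, so that exchange stays open. It cannot be told apart from a growth state of the culture, such as oxygen supply or density, because the hypoxia list splits the libraries in the same way, and its median in vector control 1, -2.12 from the other controls on the log2 scale (35 of 36 members lower), raised the growth state as a candidate explanation and does not test it. Without culture records a single wrong label or another difference in handling stays open too.

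The higher interferon-stimulated genes in ATM KO cells may in part come from low values in vector control 1. Without it the list stayed past the threshold (adjusted p = 0.0179, 41 of 66 positive) but its median fell from 0.48 to 0.14, and with an estimated correlation p was 0.249, so its share cannot be told apart from that of the knockout. Immune cells in the ATM KO cultures are not excluded either, because the 4 tested immune markers went both ways with a median of -0.26 and an SD of 1.24. Csf1r and Cd14 were higher and Lcp1 and Cd68 lower, and Coro1a stayed at or under 12.7 everywhere. The knockout itself remains an open explanation, as does the exchange with ATM KO 3, under which the list had an adjusted p of 0.317.

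With the hypoxia covariate the median of the mitochondrially encoded mRNAs was 0.82 beside 0.96 without it. The list stayed past the threshold by camera at the preset correlation (adjusted p = 1.24e-04). Without the covariate it missed at an estimated correlation (0.304) and by fry (0.281). The covariate cannot set the rise apart from the axis of vector control 1: it fits 1 slope, and the groups ran opposite ways. In controls the list mean was 0.18 in vector control 1, low in hypoxia genes, and -0.62 and -0.86 in the other controls. In ATM KO 2, also low in them, it was 0.28, against 0.40 and 0.62 in ATM KO 1 and 3. Library depth does not order these mRNAs: of the 3 libraries with the highest list mean 1 was among the 3 deepest, ATM KO 1, the deepest of all 6 (32341508 reads), while ATM KO 3 and ATM KO 2 were the shallowest (22494919 and 26223323). A difference in RNA selection or in mitochondrial content between cultures was not tested, and 7 genes from 1 polycistronic genome are not independent. An effect of the knockout, the axis of vector control 1, such a difference and the exchange with ATM KO 3 all stay open.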
